A study of Mus musculus with 12 samples.

How the data were processed

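RNA from 2 cell fractions of the testis, Sertoli cells and germ cells, was measured in 6 male C57BL/6J mice with 1 array per fraction and mouse, which gave 12 arrays. Per the labels' protocols, the whole testis was removed, germ and Sertoli cells were isolated, RNA was extracted with Trizol, and cRNA was labelled with Cy3. The arrays are 1-colour Agilent mouse arrays with 44397 spots in the files. Per the file headers, the images were read with Agilent Feature Extraction 10.7.3.1, and the array grid names genome build mm9. The deposited intensity used here is the processed signal, which per the file headers was background-subtracted and detrended within the array by the scanner software and not normalised between arrays. The deposited intensity columns with the median spot brightness and the median local background are uncorrected, per the file headers. The authors also deposited a table of log2 values. The columns of that table have nearly the same median, and across its 39429 probes the order is that of the processed signal of the same array (Spearman's rho 1), as after quantile normalisation. The column medians are 8.29, and a larger value means more signal. The submitters' processing notes name limma without further steps.

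Groups were taken from the source names, which give 3 knockout mice (120, 86 and 72) and 3 control mice (99, 73 and 74). The sample titles call control mice 73 and 74 het, while their source name says wildtype, and only mouse 99 is titled WT. Mouse 120 was 4 months old, mouse 99 was 5 months old and the others 8 months. The arrays came from 3 slides with 4 arrays each. Each slide held both fractions of 1 knockout and 1 control mouse (slide 1 mice 120 and 99, slide 2 mice 86 and 73, slide 3 mice 72 and 74). Slides 1 and 2 were scanned on the same day and slide 3 on another. Slide, and with it scan day, is therefore balanced between the genotypes, while both younger mice share slide 1.

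Control spots (1377) and spots that the scanner software called outliers were left out, and spots of the same probe were averaged. Each array's processed signal was taken as log2 and the array's 75th percentile was subtracted. Levels below are on this scale, log2 relative to the 75th percentile. Of 39429 probes, 26055 were named by matching their accession, without version, to the RefSeq table of assembly GRCm38.p6. The other 13374 kept the name in the file. That table served for names and for which genes neighbour each other, and no coordinates are given because its build differs from the array's. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 30522 probes. A gene with several probes was represented by the probe with the highest mean signal, chosen without regard to group. This left 25020 genes, of which 16583 had a symbol.

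Differences were tested with limma 3.58.1 (R 4.3.3) on 4 group means over all 12 arrays, with moderated statistics, and p-values were adjusted by the Benjamini-Hochberg method over the 25020 genes. The threshold was an adjusted p of 0.05. The comparisons were knockout against control in germ cells, knockout against control in Sertoli cells, Sertoli against germ cells in controls and in knockouts, and the difference between the knockout effects of both fractions (the interaction term, Sertoli minus germ). Changes are log2 differences with the standard error (SE) of the fit, 3 mice per group. Where a probe was not well above background on any array of the dimmer group, the fold is a lower bound. It sets the brighter group's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. No bound was computed where another probe of the gene was well above background in that group. The 28 gene lists, written from general knowledge of the testis, were tested with camera (limma) at its preset correlation between genes of 0.01 and adjusted over the 27 lists with at least 3 tested genes. Camera with an estimated correlation, and fry, were run beside it. Fry tests whether the genes of a list move on balance in the same direction, without comparing them with other genes.

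The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays do not overlap, and where fewer passed, the genes with the smallest p up to 10, given as values that did not pass. For the interaction term it names 5 per direction. Only genes with an approved-style symbol are named. Trp73, Trp53 and Trp63 are always given. Of each list, members past the threshold may be named, and otherwise the 3 with the smallest p.

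Both fractions of a mouse come from the same animal, so the mouse numbers pair the arrays. The deviations from the group mean correlated between the 2 fractions of a mouse with r 0.203 (mouse 72), -0.115 (73), 0.462 (74), 0.283 (86), -0.162 (99) and 0.256 (120) across genes, and the array of the other fraction that correlated best was the mouse's own for mice 74 and 120. The fit has no mouse term, and a fit with mouse as a block was run beside it for the comparisons between fractions.

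The fit was tested on simulated arrays with the means and spread of the real ones and 200 changed genes among 24872. For the germ comparison it recovered 16.5% of genes changed 2-fold, 70% of those changed 4-fold and 94% of those changed 16-fold. For the Sertoli comparison these shares were 6%, 71.5% and 93%, for the interaction term 0%, 41.5% and 81.5%, and for the fractions of control mice 0%, 67.5% and 94.5%. At 16-fold, 9 unchanged genes were called for germ, 14 for Sertoli, 13 for the interaction term and 21 for the fractions. Recovered genes there numbered 188, 186, 163 and 189. The shares for the fractions do not carry over to the real arrays, where 19112 of 25020 genes passed. With so many changed genes the Benjamini-Hochberg cut-off is less strict. Of 3 simulated lists of 20 genes shifted by 0.5 (log2) in the germ comparison, camera recovered 3 at the preset and 2 at the estimated correlation, with 0 false calls at either. The simulated genes were independent and the lists drawn at random, so this says nothing about false calls in lists of correlated genes.

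The alternatives were normexp background correction (offset 50) with quantile normalisation, quantile normalisation of the processed signal, the authors' log2 table, no filter and a filter over all 12 arrays, the mean of a gene's probes, each probe on its own, slide as a block and within each slide, mouse as a random and as a fixed block, only the arrays compared, each mouse left out, age as a covariate, the 8-month mice alone, array weights, a variance trend with robust estimation, an adjusted p of 0.10, and a minimum log2 change of 1. Normexp was run on the median spot signal because the mean is not among the columns. After the data had been seen, the fits without the control Sertoli array of mouse 74 and without both mice titled het were added. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.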

Results

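Gene expression was measured in Sertoli cell and germ cell fractions from the testes of 3 mice labelled TAp73 knockout and 3 labelled control, with 1 array per fraction and mouse (12 arrays in 4 groups of 3). TAp73 is the form of the p53 family member encoded by Trp73 that carries the transactivation domain. The title of the series names germ cell adhesion and maturation as its subject, so the comparisons ask which genes differ between knockout and control mice in each fraction, and whether genes of adhesion and of germ cell stages are among them. Of the probes, 77.3% ± 1.92 (SD, n = 3) were well above background on the knockout germ arrays, 75.6% ± 2.04 on the control germ arrays, 66.0% ± 1.77 on the knockout Sertoli arrays and 65.8% ± 2.16 on the control Sertoli arrays. The 75th percentile of the processed signal ranged from 1355 to 5350 over the arrays. The lowest value was that of the control Sertoli array of mouse 74. Across genes, which are not independent replicates, arrays of the same group correlated with r from 0.969 to 0.993, and germ with Sertoli arrays from 0.507 to 0.597. The first principal component held 93.8% of the variance and separated the fractions. The number of arrays limits the precision. The words germ cells and Sertoli cells below stand for the labels of the fractions, since most Sertoli cell markers were lower in the fraction labelled Sertoli.

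Trp73, the targeted gene, gave signal in all 6 knockout arrays on each of its 3 probes, and none of the probes had a lower mean in knockout than in control mice. The probe with the highest signal, A_52_P410636, lay at -1.91, -2.79 and -2.35 in the germ cells of knockout mice 120, 86 and 72, and at -4.28 and -2.68 in those of control mice 99 and 74, with mouse 73 between them. In Sertoli cells it lay at -2.91, -2.82 and -2.72 in the knockout and at -3.56, -4.01 and -2.13 in the control mice. The means were -2.35 ± 0.44 in knockout and -3.35 ± 0.83 in control germ cells (SD, n = 3), a difference that did not pass (limma with Benjamini-Hochberg adjustment, adjusted p 0.753). In Sertoli cells the log2 difference was 0.42 ± 0.50 and did not pass either. A_52_P193555 was not well above background in either fraction of mouse 99, the only control titled WT, at -9.40 in germ cells and -9.42 in Sertoli cells. In the controls titled het it lay at -3.63 (mouse 73) and -4.15 (mouse 74) in germ cells and at -2.50 and -3.22 in Sertoli cells, and in the knockout mice between -3.29 and -1.52 over both fractions. A_55_P1988133 lay at -8.73 in germ cells of mouse 99, at -5.10 and -4.39 in those of mice 73 and 74, and between -4.39 and -3.50 in those of knockout mice. In Sertoli cells it lay at -8.52, -6.67 and -5.39 in control mice 99, 73 and 74, not well above background in any of them. In the Sertoli cells of knockout mice 120, 86 and 72 it lay at -5.43, -5.82 and -5.55, well above background in each. The sources used here do not say which part of Trp73 was deleted or where these probes lie in it. A probe outside the deleted part checks nothing about the deletion, so the words knockout and control below stand for the labels.

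**Figure D1:**
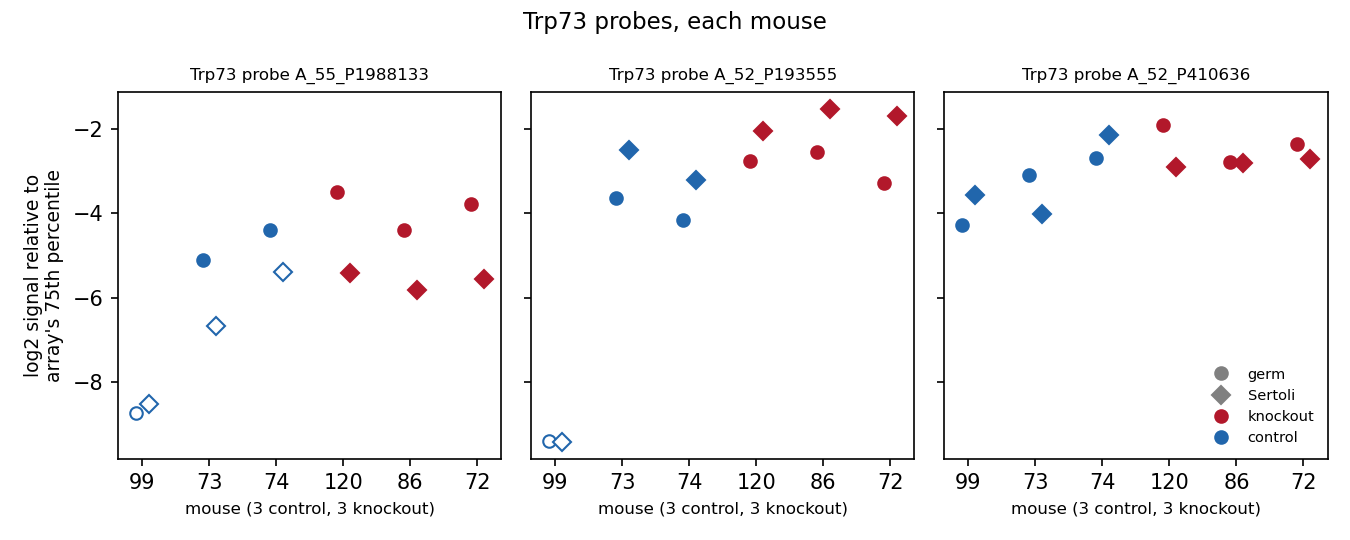
Signal of the 3 Trp73 probes (log2 relative to each array's 75th percentile, vertical axis) in each mouse (horizontal axis), in germ cells (circles) and Sertoli cells (diamonds) of control (blue) and knockout (red) mice. Open symbols were not well above background, as for A_52_P193555 in mouse 99 at -9.40 and -9.42.

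In the germ cell fraction 54 genes rose in knockout mice, Gpnmb, Spp1 and Timp1 among them. Taste receptor gene Tas1r1 was the only gene to fall. The lists of cytokine and interferon genes, immediate early genes, peptidases, basement membrane and apoptosis genes rose as sets. Markers of macrophages and leukocytes (median 1.04), Leydig cells (1.24) and Sertoli cells (0.50) rose in the same fraction by camera, and spermatid and spermatocyte markers lay slightly lower. All of these marker calls were lost with an estimated correlation. Of 25020 genes, 54 rose and 1 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 1837 had an unadjusted p under 0.05, of which 1529 were higher in knockout mice. With normexp background correction 63 rose and 9 fell, so that 87.5% of the calls were higher against 98.2% here. In 3920 genes (15.7%) the 3 knockout arrays did not overlap the 3 control arrays, where chance gives 10%. The count rests on single mice. It was 3 without mouse 72, 3 without mouse 73, 30 without mouse 74, 3 without mouse 86, 4 without mouse 99 and 130 without mouse 120.

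Gpnmb, which encodes a transmembrane glycoprotein, rose by 5.72 ± 0.92 on the log2 scale (limma, adjusted p 0.0434) and by 2.79, 7.73 and 6.63 on the slides. Over the other alternatives, without the values within slides, it rose by 2.79 to 7.29. Spp1, which encodes osteopontin, rose by 5.45 ± 0.47 (adjusted p 0.00195), by 4.19, 6.16 and 6.00 on the slides and by 2.69 to 6.08 over the other alternatives. Both were well above background on only 1 of 3 control germ arrays, that of mouse 99 in each case, so the size of these changes is uncertain. Timp1, an inhibitor of metalloproteinases, rose by 4.05 ± 0.44 from -3.98 ± 0.43 to 0.07 ± 0.90 (mean ± SD, n = 3). The small heat shock gene Hspb8 rose by 3.38 ± 0.44. The adhesion gene Mpzl2 rose by 3.25 ± 0.24 and shared the smallest adjusted p, 0.000648, with Tas1r1. Ccl7 was not well above background on any control germ array and was at least 6.36-fold higher in knockout mice (adjusted p 0.0423). Aqp5 and Igfbp3 both rose by 3.07, with an SE of 0.42 and 0.32. Wfdc18 rose by 3.06 ± 0.51 and Adam23 by 2.89 ± 0.34. The calls of Spp1, Mpzl2 and Tas1r1 passed without any 1 of the 6 mice, with adjusted p up to 0.0471, 0.0335 and 0.0335. Those of Timp1, Hspb8, Igfbp3 and Adam23 were lost without mouse 72, 73, 86 or 99, with adjusted p up to 0.140, 0.161, 0.120 and 0.140. Gpnmb was lost without any mouse but 99 (up to 0.402), and Ccl7, Aqp5 and Wfdc18 without any mouse but 120 (up to 0.371, 0.237 and 0.411). Over all alternatives the adjusted p reached 0.137 for Spp1 and 0.0865 for Mpzl2.

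Tas1r1 fell by 5.28 ± 0.37 on the log2 scale in germ cells (limma with Benjamini-Hochberg adjustment, adjusted p 0.000648), from -0.24 to -5.52. On the 3 slides the changes were -6.13, -5.34 and -4.38. In control mice Tas1r1 was lower in the Sertoli than in the germ fraction, with a difference of -5.34. In the RefSeq order of assembly GRCm38.p6 Tas1r1 lies 21 tested genes from Trp73 on the same chromosome. With only the 8-month mice, 2 per genotype, its adjusted p was 0.0541, the highest over the alternatives, and the lowest was 2.2e-06. Cd276 had the next smallest p among named genes that lay lower, with a difference of -1.75 ± 0.37 that did not pass (adjusted p 0.112). Nor did Sema3a (not well above background on any germ array), Pou4f2 (-1.54), Tspan6 (-0.75), Dydc2 (-0.70), Nqo2 (-0.70), Noxred1 (-0.67), Ccdc159 (-0.59) and Inpp5j (-0.56), with adjusted p from 0.182 to 0.307. Trp53 differed by 1.28 ± 1.70 and Trp63 by -0.02 ± 0.36, neither past the threshold. The other tested probe of Trp63 pointed the other way. Trp63 lay at 1.27 ± 0.24 (mean ± SD, n = 3) in knockout germ cells.

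**Figure D2:**
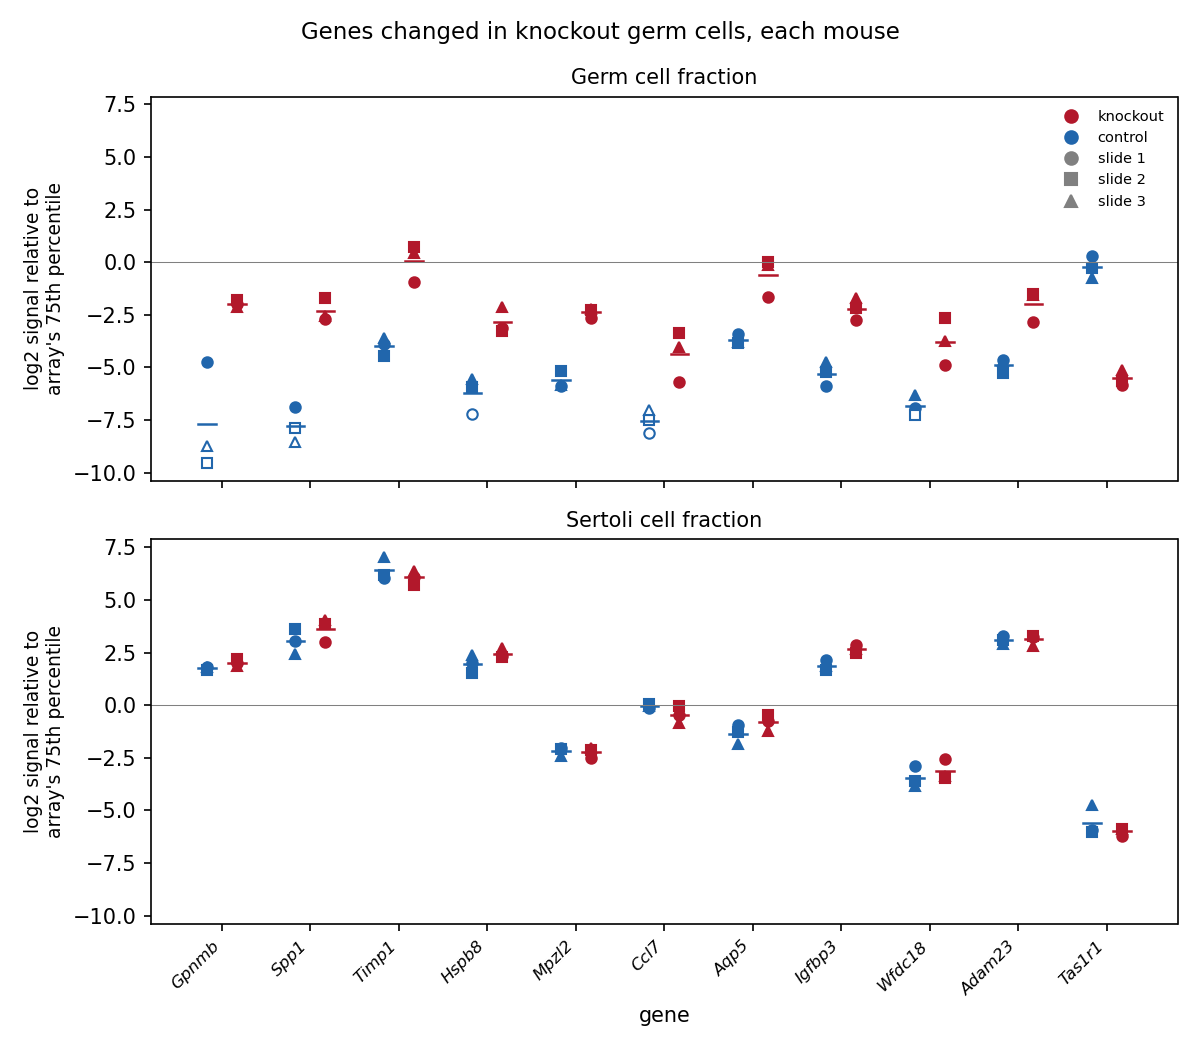
Signal (log2 relative to each array's 75th percentile, vertical axis) of the 10 named genes that rose and of Tas1r1, which fell, in germ cells (top) and Sertoli cells (bottom) of each control (blue) and knockout (red) mouse, with the mean of 3 mice as a line. Symbols give the slide (open, not well above background), and Timp1 moved from a mean of -3.98 to 0.07 in germ cells, and Tas1r1 from -0.24 to -5.52.

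Of the other genes that rose in germ cells, those in this paragraph outside the lists were chosen after their values were seen. The receptor genes Trem2 (2.81), Tnfrsf12a (2.68) and Gpr176 (2.88) rose, as did Wnt10a (2.60), the kinase gene Syk (2.40), Rab7b (2.33), Lcp1 (2.29), Fst (2.22), Maf (2.10), Pdpn (2.05), Ccn5 (1.94) and Edn1 (1.75), each with a limma adjusted p under 0.05. Of the 54 risers, 48 were also higher in the Sertoli than in the germ fraction of control mice, where 21.5 would be shared by independent lists. Arrays simulated without any change against the same control germ arrays gave 25.3 on average over 20 simulations (17 to 33). They were drawn around the observed control germ means, so chance deviations of the control arrays did not enter the simulated rises. The simulation therefore cannot show how much of the 48 the shared control arrays give. In the knockout mice, 38 of the 54 were higher in the Sertoli than in the germ fraction (20.5 by independent lists). The control count shares the control germ arrays with the germ comparison, and 3 controls cannot be split, so part of its excess may come from the shared arrays. The exceptions include Cxcl1, which was lower in the Sertoli fraction of control mice with a log2 difference of -2.90, Ahsg (-1.52) and Ldhd (-1.02).

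Of 27 gene lists, 18 were called in germ cells by camera at its preset correlation (15 up, 3 down), and 5 of them held with an estimated correlation. Fry called 13. Counts per list below were adjusted over the list alone, with the count over all genes beside them. The cytokine and interferon list had a median log2 change of 1.11, with 16 of 16 genes higher (camera adjusted p 7.4e-14, and 0.0369 with an estimated correlation). It had 8 genes that rose when adjusted over the list alone and 1 over all genes, Cxcl1 (2.48, adjusted p 0.00861), beside Cxcl2 (2.58) and Ccl2 (2.26), which did not pass over all genes. Immediate early genes had a median of 0.93, with 16 of 17 higher (p 0.00239 with an estimated correlation). Of these 5 rose when adjusted over the list alone and 1 over all genes, Ccn1 (1.51). Matrix and lysosomal peptidases had a median of 0.61 (p 0.0334 with an estimated correlation), with 7 risers adjusted over the list alone and 2 over all genes, Mmp23 (2.53) and Ctsk (1.31). Basement membrane genes had a median of 0.45, with 18 of 24 higher (p 0.00919 with an estimated correlation) and 5 risers adjusted over the list alone against 0 over all genes by limma, with Col4a1 (0.92) and Lamb2 (1.11) among the 3 of smallest p. Apoptosis genes had a median of 0.29 (p 0.0334 with an estimated correlation), with 6 risers adjusted over the list alone against 0 over all genes, Casp8 (1.40) foremost. These 5 calls at the preset correlation remained without any 1 of the mice, and the apoptosis call was lost without both mice titled het (camera adjusted p 0.0984, the highest over its alternatives, against a lowest of 4.56e-05).

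Adhesion lists and markers of other cell types rose by camera in germ cells, but these calls were lost with an estimated correlation. Adherens junction, ectoplasmic specialization and desmosome genes had a median of 0.31 (p 0.114 with an estimated correlation). They had 2 risers adjusted over the list alone and 0 over all genes, with Cdh1 (1.05), Zyx (0.75) and Nectin2 (0.56) foremost. Without mouse 99 the call was lost (camera adjusted p 0.0695). Integrins and focal adhesion genes had a median of 0.38 (p 0.116 with an estimated correlation), 0 risers adjusted over the list alone or over all genes, and a call lost without mouse 99 (camera adjusted p 0.119). Tight junction genes did not move as a set (median 0.02, camera adjusted p 0.906). Macrophage and leukocyte markers had a median of 1.04 (p 0.0970 with an estimated correlation), with 9 risers adjusted over the list alone and 0 over all genes, Lyz2 (2.73), Cd14 (1.24) and Tyrobp (2.04) foremost. Leydig cell markers had a median of 1.24 (p 0.0754 with an estimated correlation), with 3 risers adjusted over the list alone and 0 over all genes, Cyp11a1 (2.02) foremost with an adjusted p of 0.0505. Sertoli cell markers had a median of 0.50 (p 0.0754 with an estimated correlation) with 20 of 21 higher and 0 risers adjusted over the list alone. Fibroblast markers had a median of 0.77 (p 0.0970 with an estimated correlation) with Pdgfra (1.25) as the 1 riser on either count, and peritubular myoid markers 0.47 (p 0.116 with an estimated correlation) with 2 risers adjusted over the list alone and 0 over all genes. Peptidase inhibitors had a median of 0.39 (p 0.0514 with an estimated correlation), with 6 risers adjusted over the list alone and 1, Timp1, over all genes. P53 family targets had a median of 0.31 (p 0.0633 with an estimated correlation), with 2 risers adjusted over the list alone and 0 over all genes, and Phlda3 (1.24), Fas (1.87) and Cdkn1a (0.65) foremost. The retinoid list had a median of 0.17 (p 0.0970 with an estimated correlation), with 1 riser adjusted over the list alone and 0 over all genes. Its median level was lower in knockout germ arrays, at -0.73 against -0.47 in controls (means of 3 arrays), so its direction depends on the summary used.

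Markers of germ cell stages lay lower in knockout germ cells by small amounts. Elongating spermatid markers had a median log2 change of -0.36, with 16 of 18 lower (camera adjusted p 0.00592, and 0.502 with an estimated correlation). Round spermatid markers had a median of -0.28, with 12 of 13 lower (p 0.238 with an estimated correlation), and spermatocyte markers -0.12, with 20 of 26 lower (p 0.502 with an estimated correlation). In each of these 3 lists 0 genes fell when adjusted over the list alone or over all genes by limma, and Tssk6 (-0.59), Spaca1 (-0.42) and Syce2 (-0.52) had the smallest p. The round spermatid call was lost without mouse 72 (camera adjusted p 0.0691) or 99 (0.0532), and the spermatocyte call without mouse 72 (0.174), 73 (0.0503) or 99 (0.0931). Both were also lost under each of the 3 other scalings. Spermatogonia markers had a median of -0.04, a mean of 0.04 and a test direction upward, with a camera adjusted p of 0.741. The remaining lists were not called in germ cells. These were endothelial (median 0.25), erythroid (-0.06, mean 0.07 and test upward), mitotic cell cycle (-0.13), multiciliation (-0.10), heat shock (0.07, with Hspb1 as 1 riser adjusted over the list alone and 0 over all genes), cholesterol synthesis (0.10) and antioxidant genes (0.01), with camera adjusted p from 0.0668 to 0.519. Of the epididymis list only Rnase10 was tested, at -0.21.

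**Figure D3:**
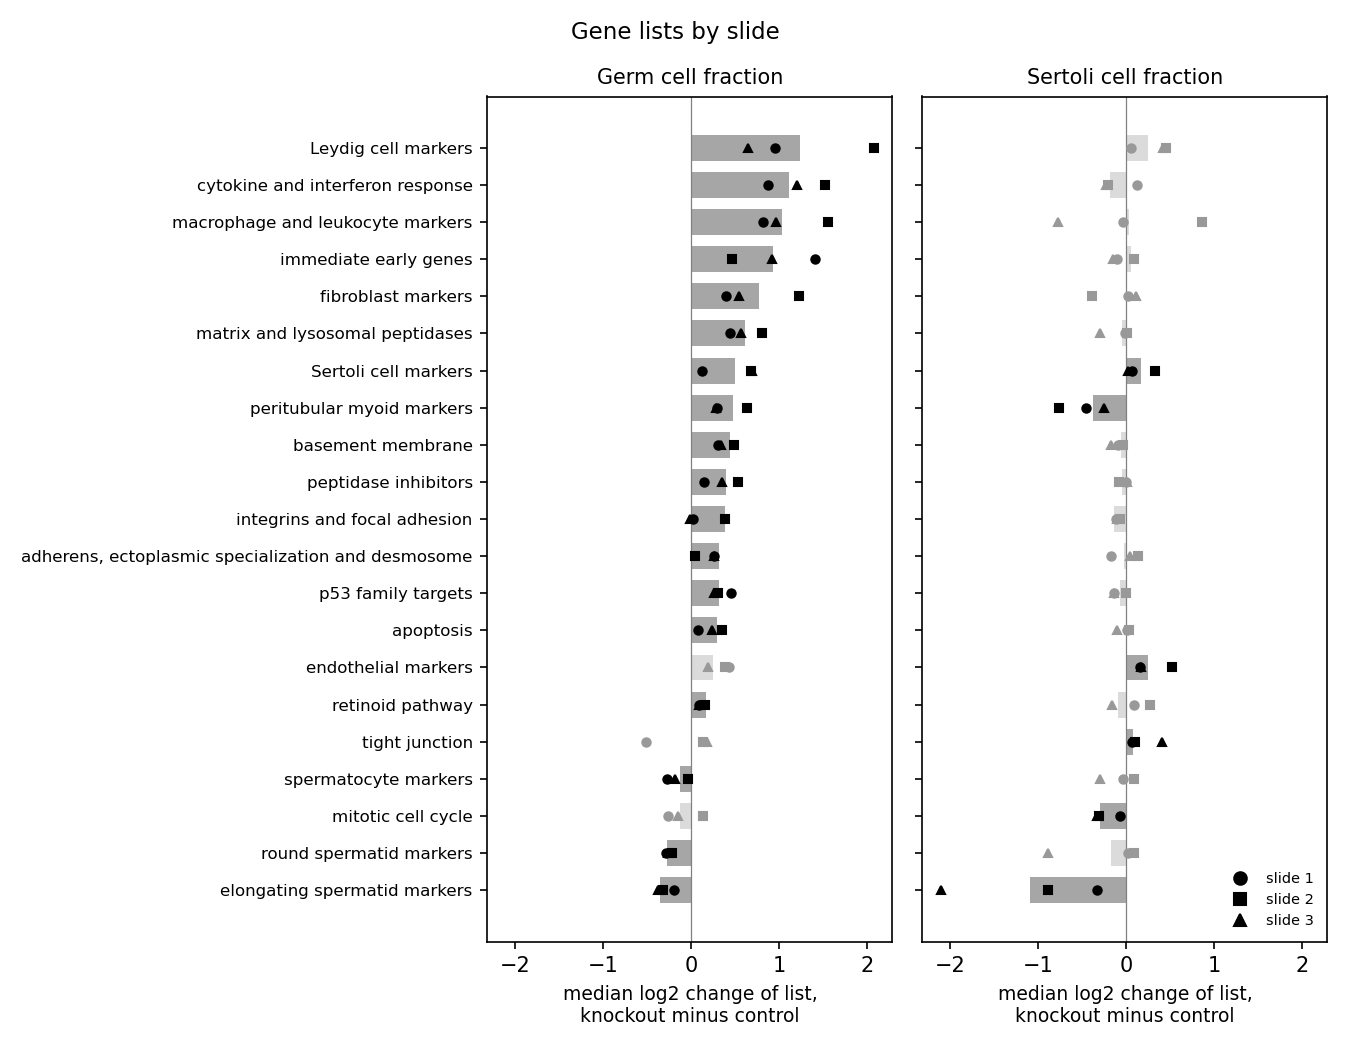
Median log2 change, knockout minus control (horizontal axis), of the gene lists called in either fraction, in germ cells (left) and Sertoli cells (right). Bars give the list's median, symbols the median within each slide, and dark bars with black symbols the lists called by camera at its preset correlation; elongating spermatid markers lay at -0.36 in germ cells and -1.10 in Sertoli cells.

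The Sertoli fractions of knockout and control mice did not differ in any single gene past the threshold. Transcripts of elongating spermatids were lower in the knockout Sertoli fraction as a set by camera at its preset correlation, and Sertoli cell markers were slightly higher. Both calls were lost with an estimated correlation (adjusted p 0.441 for each). Of 25020 genes, 0 were called (limma with Benjamini-Hochberg adjustment, smallest adjusted p 0.152) and 757 had an unadjusted p under 0.05, of which 595 were lower in knockout mice. In 1670 genes (6.70%) the groups did not overlap, where chance gives 10%. The median of all genes was -0.10. Without mouse 99, 5 genes fell. The named genes with the smallest p that lay higher were Ak7 (1.21 ± 0.25, adjusted p 0.480), Clec1a (1.51), Tacr3 (1.23), Calcb (1.01), Tex19.1 (1.16), Palmd (0.94), Plac1 (2.29), Cda (0.57), Gabra3 (1.03) and Mxd1 (0.63). Ak7, Clec1a and Plac1 were well above background on only 1 of 3 control Sertoli arrays, so the size of their differences is uncertain. Those that lay lower were Pax9 (at least 1.70-fold, adjusted p 0.196), Slc2a5 (-1.39 ± 0.25), Slc45a1 (-1.21 ± 0.23), Fam167a, Kcnc1, Pdilt, Lmntd1, Pcdha12, Pip and Nt5c1b. The last 7 were not well above background on any knockout Sertoli array, and Pdilt, Lmntd1, Pcdha12, Pip and Nt5c1b not on any control Sertoli array either, so no fold is given for them and their order rests on signal at background. Slc2a5 and Slc45a1 lie 37 and 33 tested genes from Trp73 in the RefSeq order of GRCm38.p6. Trp53 differed by 0.88 ± 1.70 and Trp63 by -0.46 ± 0.36, and neither passed. The other tested probe of Trp63 pointed the other way.

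Camera called 6 lists in Sertoli cells at the preset correlation, 3 up and 3 down. None held with an estimated correlation, where the smallest adjusted p was 0.441 and 8 lists had an unadjusted p under 0.05 at the preset. Fry called 0. Without mouse 73 only 1 list was called. Elongating spermatid markers had a median of -1.10, with 18 of 18 lower (camera adjusted p 1.21e-12, and 0.441 with an estimated correlation). Of these, 9 fell when adjusted over the list alone and 0 over all genes, and Tnp2 (-1.33), Prm3 (-1.68) and Prm1 (-1.51) had the smallest p. The list's median level was -5.22, -4.73 and -3.75 in control mice 99, 73 and 74, against -5.47, -5.50 and -5.19 in knockout mice 120, 86 and 72. Without the control array of mouse 74 the median change was -0.57. Peritubular myoid markers lay at -0.38, with 9 of 9 lower (p 0.441 with an estimated correlation) and 1, Actg2, fallen when adjusted over the list alone (-0.75), 0 over all genes. That call was lost without mouse 73 (0.0605), 86 (0.0717) or 99 (0.0837). Mitotic cell cycle genes lay at -0.29 (p 0.683 with an estimated correlation), a call lost without mouse 72 (0.811), 73 (0.767) or 99 (0.140). Sertoli cell markers lay at 0.17, with 16 of 21 higher (p 0.441 with an estimated correlation), a call lost without mouse 73 (0.0605) or 74 (0.461). Endothelial markers lay at 0.25 (p 0.670 with an estimated correlation), a call lost without mouse 72 (0.259) or 73 (0.767). Tight junction genes lay at 0.08 (p 0.441 with an estimated correlation), with Cldn5 (0.83), Cgn (0.53) and Cldn11 (0.69) foremost, a call lost without mouse 72, 73, 74 or 86 (adjusted p up to 0.686). In these last 4 lists 0 genes passed when adjusted over the list alone.

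The other lists were not called in Sertoli cells (camera adjusted p from 0.0848 to 0.955). Their medians were 0.25 for Leydig cell markers, 0.01 for apoptosis, 0.03 for macrophage and leukocyte markers, -0.02 for spermatogonia, 0.01 for cholesterol synthesis, -0.09 for retinoid, -0.02 for adherens junction, -0.17 for erythroid, -0.02 for multiciliation, -0.17 for round spermatid, -0.00 for fibroblast, -0.05 for peptidase inhibitors, -0.14 for integrins, -0.10 for antioxidant, -0.05 for peptidases, 0.06 for immediate early, -0.19 for cytokine and interferon, -0.13 for heat shock, -0.07 for p53 family target, 0.02 for spermatocyte and -0.06 for basement membrane genes. The test pointed upward although the median was below 0 for the spermatogonia, retinoid, adherens junction, erythroid, multiciliation, fibroblast, peptidase inhibitor, peptidase, p53 family target and basement membrane lists, where all genes had a median of -0.10. For spermatocyte markers the mean was -0.12 and the test pointed upward. Of the epididymis list Rnase10 lay at -0.21. Among erythroid markers 1 gene, Alas2 (0.63), rose when adjusted over the list alone and 0 over all genes.

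The Sertoli and germ cell fractions of control mice differed in most genes. By camera at its preset correlation, lists of spermatocyte and spermatid markers were lower in the Sertoli fraction, and lists of fibroblast markers and basement membrane genes were higher. Of these, only the basement membrane call held with an estimated correlation. The list of Sertoli cell markers itself was not higher in the Sertoli fraction. Of 25020 genes, 9966 were higher and 9146 lower in the Sertoli fraction (limma, Benjamini-Hochberg adjusted p under 0.05), 520 by at least 64-fold and 2266 lower by as much. In 75.1% of genes the arrays did not overlap, where chance gives 10%. In knockout mice 9492 were higher and 9284 lower, and 80.9% did not overlap. The median of all genes was 0.21 in control mice and 0.44 after quantile normalisation, so changes near that size have no settled direction. Cxcl14 was higher by 12.86 ± 0.34 on the log2 scale, S100a4 by 10.96 ± 0.42, Sfrp2 by 10.83 ± 0.31, Timp1 by 10.40 ± 0.44 and Ccn5 by 10.31 ± 0.32. Spp1 was higher by 10.80, with 1 of 3 germ arrays well above background. Inhba was at least 1681-fold higher, Col5a2 at least 319-fold, Aldh1l2 at least 498-fold and Ankrd1 at least 699-fold, none of them well above background on a control germ array. Of the 10 named genes lower in the Sertoli fraction, none was well above background on a control Sertoli array. Slc22a16 was at least 2981-fold lower, Gtf2a1l at least 2719-fold, Iqcf5 at least 2377-fold, Tmbim7 at least 2289-fold, Ccer1 at least 1953-fold, Armc3 at least 1729-fold, Spag6l at least 1616-fold and Efcab5 at least 1491-fold. No fold is given for Adcy10 and Rpl10l, because another of their probes was measured there. Trp73 differed by 0.12 ± 0.50, Trp53 by 3.34 ± 1.70 and Trp63 by -0.78 ± 0.36 between the fractions, and none passed (limma adjusted p 0.839, 0.0948 and 0.0649). On the slides Trp53 differed by 8.83, -1.26 and 2.45, so its sign was not shared. For Trp73 and Trp63, 1 other tested probe of the gene pointed the other way.

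Camera called 15 lists between the fractions of control mice (10 higher, 5 lower in the Sertoli fraction), of which 1, the basement membrane list, held with an estimated correlation. Fry called 26 of 27. Elongating spermatid markers lay at -9.87 (p 0.197 with an estimated correlation), spermatocyte markers at -8.06 (0.0652), round spermatid markers at -7.41 (0.0652), multiciliation genes at -5.74 (0.0652) and mitotic cell cycle genes at -1.99 (0.396 with an estimated correlation). In the first 3 of these all 18, 26 and 13 genes were lower, over all genes and adjusted over the list alone, among them Odf1 (-12.26), Stag3 (-8.66) and Spata16 (-12.01). Fibroblast markers lay at 6.75 (0.0652 with an estimated correlation), with 9 of 9 higher on both counts, Col3a1 (8.95) and Pdgfra (6.67) among them. Peritubular myoid markers lay at 5.77 (0.0762), basement membrane genes at 4.93 (0.0102), peptidases at 4.81 (0.0652), integrins at 3.78 (0.0652), p53 family targets at 3.30 (0.0652), antioxidant genes at 3.16 (0.0652), cholesterol synthesis at 2.60 (0.0652), immediate early genes at 2.10 (0.0777) and apoptosis genes at 1.95 (0.0762, each with an estimated correlation). Sertoli cell markers lay at -0.83, and the list was not called (camera adjusted p 0.151). Over all genes and adjusted over the list alone, 7 of the 21 were higher in the Sertoli fraction, including Kitl (4.38), Inhbb (3.39) and Sox9 (1.43), and 11 were lower, including Tsx (-8.11), Cst9 (-8.03), Fshr (-5.30), Rhox5 (-5.28) and Dhh (-2.16). Macrophage markers lay at -1.81, tight junction genes at -1.98, spermatogonia markers at -0.88, Leydig cell markers at -0.67, erythroid markers at -4.61, endothelial markers at 0.87, the heat shock list at 2.15, peptidase inhibitors at 2.32, cytokine and interferon genes at 4.15, retinoid genes at 1.18 and adherens junction genes at 1.58, none of them called (camera adjusted p from 0.0751 to 0.659).

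The effect of the knockout differed between the fractions for Tas1r1 and Mpzl2 by the interaction term. Tas1r1 lay between -6.05 and -4.76 in control Sertoli cells, near the lower end of the scale, so a fall of the size seen in germ cells could not have been measured there and its difference is partly set by that level. By the interaction term, 2 of 25020 genes passed (limma, Benjamini-Hochberg adjusted p under 0.05) and 1145 had an unadjusted p under 0.05. For Tas1r1 the difference, Sertoli minus germ, was 4.87 ± 0.52, and for Mpzl2 -3.29 ± 0.34 (adjusted p 0.0251 for both). With mouse as a block 0 genes passed, with an adjusted p of 0.228 for Tas1r1 and 0.103 for Mpzl2. Without mouse 72, 73 or 86 the count was 0, without 74 or 99 it was 1 and without 120 it was 3. Without mouse 74 the gene was Tas1r1, while neither Tas1r1 nor Mpzl2 was among those called without mouse 99 or 120. The call of Tas1r1 was lost without any mouse but 74 (adjusted p up to 0.622), and that of Mpzl2 without any of the 6 (0.0514 to 0.622). The next genes by p, which did not pass, were Tnfrsf12a (-2.91), Spp1 (-4.86), Ccn1 (-1.56) and Timp1 (-4.40), each with an adjusted p of 0.106. Among those with a difference above 0, Cd276 (2.03), Calcb (1.35) and Ak7 (1.12) did not pass either (adjusted p from 0.579 to 0.813). For Trp73 the difference was -0.59 ± 0.71, for Trp53 -0.41 ± 2.40 and for Trp63 -0.43 ± 0.50. Of Trp73 and of Trp63, 1 other tested probe pointed the other way.

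Of the lists, 12 were called by the interaction term (1 up, 11 down), 2 of which held with an estimated correlation, and fry called 10. With mouse as a block 11 were called. The immediate early list lay at -0.89 (p 0.00718 with an estimated correlation) and the basement membrane list at -0.40 (0.0231 with an estimated correlation). The cytokine and interferon list lay at -1.17 with 16 of 16 genes below 0 (p 0.0508 with an estimated correlation), and 8 passed when adjusted over the list alone against 0 over all genes. The spermatocyte list had a median of 0.23, was not called (camera adjusted p 0.0582), and neither was the Sertoli marker list (-0.31, 0.0582). Median and mean or test differed in sign for spermatogonia (-0.15, test upward), erythroid (-0.11, test upward), endothelial (0.10, mean -0.06) and round spermatid markers (0.05, mean -0.02), none of them called. Across genes, which are not independent replicates, the knockout effects in the germ and Sertoli fractions correlated with r 0.217 and Spearman's rho 0.242. Within the slides r was 0.0867, -0.263 and 0.230. Both effects come from the same mice. Of the 10 splits of the mice into 3 and 3, 6 gave an r as high, the real one included (-0.302 to 0.474 in the others). The splits therefore show no link of the value to genotype, and 10 are too few to exclude one.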

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

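The tests of explanations for the 3 patterns below were chosen after the results were seen, while the counts over other splits of the mice were planned. The knockout effect differed between the Sertoli and germ cell fractions, by a test of the difference itself, for 2 genes (limma interaction term) and 12 gene lists (camera at its preset correlation). Sertoli minus germ, the log2 difference was -3.29 for Mpzl2 and 4.87 for Tas1r1, with an adjusted p of 0.0251 for both (0.00516 to 0.622 and 0.000398 to 0.622 over the alternatives). The call of Mpzl2 ended without any 1 of the 6 mice, that of Tas1r1 without any but mouse 74, and both ended with mouse as a block. The low level of Tas1r1 in control Sertoli cells sets part of its difference. The list medians were -1.17 for cytokine and interferon genes, -0.89 for immediate early genes, -0.61 for peptidases, -1.09 for macrophage and leukocyte markers, -0.96 for peritubular myoid markers, -0.40 for basement membrane genes, -0.56 for peptidase inhibitors, -0.43 for p53 family targets, -0.72 for Leydig cell markers, -0.71 for elongating spermatid markers, -0.52 for integrins and 0.35 for multiciliation regulators. Of these 12, the immediate early and basement membrane lists held with an estimated correlation. Without mouse 99 the calls of the Leydig, p53 target and integrin lists ended (camera adjusted p 0.158, 0.284 and 0.589). The elongating spermatid call ended without mouse 74 (0.207) or 120 (0.0767), and the multiciliation call without mouse 73 (0.199), 74 (0.112), 86 (0.244) or 99 (0.0558).

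Of the 54 genes that rose in the germ cell fraction of knockout mice, 19 were among 255 genes of the Sertoli fraction (at least 64-fold above the germ fraction, averaged over the genotypes, with a mean Sertoli level above 1), so cells like those of the Sertoli fraction in the germ cell pellets are 1 candidate explanation. The share of Sertoli-fraction RNA that the change of these 255 needs had a median of 0.379% and a 95th percentile of 1.30% (1.35%, 1.78% and 1.68% on the slides). The cut at 64-fold, which used the knockout germ arrays, itself keeps the shares of the 255 low. On all 3 slides 17 of the 54 risers needed more than 10 times the 95th percentile of the slide. This factor was set after the shares were seen. Of the 17, 5, Cxcl1 among them, needed more than 100%. Cells with the mix of the whole Sertoli fraction would add the same share to every gene. The 17 argue against such a mix as their whole source. The comparison cannot decide about cells of only a part of that fraction, which could add other shares. The other 37 may come from cells like those of the Sertoli fraction, since a smaller excess can follow from choosing genes by their rise. A lower share of germ cells would raise the markers of other cells. The macrophage median within a slide rose by 0.61 more than the Sertoli marker median as a mean of the 3 slides (0.69, 0.87 and 0.26). This cannot decide, since markers with signal from germ cells or background would rise less. In control germ arrays the macrophage list lay at -3.50 and the Sertoli marker list at 0.72. A lower share of germ cells stays open, and so does a change in the cells of the germ fraction with genotype, which was not tested.

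Tas1r1 fell in germ cells and lies 21 tested genes from Trp73, so DNA of another strain kept around the targeted gene is a candidate cause. Among the 50 tested genes on each side of Trp73, 16 of 99 (16.2%) had an unadjusted limma p under 0.05 in either fraction, against 1969 of 16482 other genes (11.9%), a one-sided Fisher exact p of 0.130. The count leaves out Tas1r1 itself. Mmp23, which passed in germ cells with a rise of 2.53, is among these neighbours, 25 tested genes from Trp73. In Sertoli cells each neighbour with an unadjusted limma p under 0.05 lay lower, as did 595 of all 757 such genes. The share lay above that of other genes without passing, so this cause stays open. A loss of the germ cells that express Tas1r1 would lower other germ cell genes with it, but the largest fall among 2920 other genes at least 32-fold higher in germ cells was -2.33, and 0 fell by 50% of the log2 fall of Tas1r1, which argues against that loss. An effect of the genotype on Tas1r1 itself stays open.

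Elongating spermatid transcripts lay lower in the Sertoli fraction of knockout mice, where carried-over germ cells are a candidate source. Of 161 other genes abundant in germ cells and measured on all 6 Sertoli arrays, 88.2% were lower in knockout Sertoli arrays (median -0.33), against 62.0% of the remaining genes measured there, so less germ cell RNA in these fractions may explain part of the pattern. Without the control Sertoli array of mouse 74 the list's median was -0.57 in place of -1.10, and 67.1% of the 161 genes were lower against 52.7%. The list was still called by camera (adjusted p 6.5e-09, and 2.01e-18 to 8.61e-05 over the alternatives) but not with an estimated correlation (0.384), and the SD of the 3 slides was 0.907, so the effect of that array and of the genotype cannot be told apart with 3 mice. A lower number of spermatids in the knockout testis would also lower the carry-over and was not tested.

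The 6 mice, or the 6 arrays of a genotype, can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In germ cells 1 of the 10 splits, the real one, gave as many genes (55, highest other 4) and 1 as many lists (18, highest other 14). In Sertoli cells the real count was 0 genes by limma (757 at an unadjusted p under 0.05). Every split must reach that count, so the gene counts decide nothing there. The highest was 10 for mice 86, 99 and 120 against the rest, and 5 splits gave as many lists (6, highest other 9). For the interaction term 1 split gave as many genes (2, highest other 0) and 2 as many lists (12, highest other 19, for mice 73, 99 and 120 against the rest). Between the fractions of control mice 1 split gave as many genes (19112, highest other 0) and 4 as many lists (15, highest other 15), and in knockout mice 1 gave as many genes (18776, highest other 0). In control mice the other splits that also part the 2 arrays of every mouse gave 0 genes and 13, 12 and 12 lists, while those that keep the 2 arrays of a mouse together gave 0 genes and 9 to 15 lists. The splits of mice 86, 99 and 120 and of mice 73, 99 and 120 put both mice of slide 1, the younger ones, against both mice of slide 3, scanned on another day, so slide, scan day or age may lie behind their counts. With slide as a block the real split gave 0 genes (limma) and 6 lists in Sertoli cells and 11 lists for the interaction term.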

How the results depend on the processing

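The fits without the control Sertoli array of mouse 74 and without both mice titled het were chosen after the data had been seen, and the other alternatives were planned. Of 216 counts under alternatives, 176 stayed within 1.5 times the value reported and 40 did not. Of 2588 list medians, 2241 moved by less than the spread of the list's medians within slides and 343 by more. The other 4 were medians of called lists that changed sign. A sign change in a list that was not called was counted only by its size. Of 1674 values of named genes, 1507 kept their direction and their side of the threshold, 102 no longer passed, 37 newly passed and 28 changed sign, all of the 28 for Trp53, Trp63 or Trp73, which did not pass in any comparison reported.

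The germ cell count of 55 became 28 without a filter, 1 with only the germ arrays, 1 without the younger mice, 2176 with array weights (80.3% higher), 111 with a variance trend, 129 at an adjusted p under 0.10, 1 without the mice titled het, and 3 to 130 with 1 mouse left out (3 without mouse 72, 73 or 86, 4 without 99, 30 without 74 and 130 without 120). Of the 55 genes, 34 were among the 72 under normexp, 44 among the 71 after quantile normalisation and 44 among the 74 in the authors' table. The Sertoli count of 0 (limma, 757 genes at an unadjusted p under 0.05) became 1 in the authors' table, 3 with array weights, 5 without the mice titled het and 0 to 5 with 1 mouse left out (5 without mouse 99). The interaction count of 2 became 1 under normexp, 1 after quantile normalisation, 1 in the authors' table, 4 with the filter on all 12 arrays, 1 with age as a covariate, 0 without the younger mice, 68 with array weights, 7 with a variance trend, 0 with mouse as a block, 0 without the mice titled het and 0 to 3 with 1 mouse left out (0 without mouse 72, 73 or 86, 1 without 74 or 99). The interaction genes counted without mouse 99 or 120 were others than Tas1r1 and Mpzl2. Lists called with an estimated correlation were 5 in germ cells, 0 in Sertoli cells, 2 for the interaction term and 1 between the control fractions. Fry called 0 in Sertoli cells and 26 between the control fractions. In Sertoli cells 3 lists were called in the authors' table and 1 to 8 with 1 mouse left out (1 without mouse 73). Fits without mice have fewer samples, and that without the mice titled het leaves 1 control mouse, assumed to vary like the other groups, the germ-only fit has fewer arrays for the spread, and the higher threshold admits more genes. For the other settings the cause was not tested.

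Signs of named genes and of the medians of called lists changed as follows, and the cause was not tested. Trp63 in germ cells (-0.023) was 0.016 under normexp, 0.040 after quantile normalisation, 0.038 in the authors' table, 0.075 as the mean of probes, 0.0034 with age, 0.097 with array weights, 0.22 without the mice titled het and -0.15 to 0.12 with 1 mouse left out. Trp63 in Sertoli cells (-0.46) was 0.0056 without the array of mouse 74 and -0.72 to 0.0056 with 1 mouse left out, and its interaction term (-0.43) was 0.029 without that array. The interaction term of Trp53 (-0.41) was 0.20 under normexp, 2.78 without the younger mice, 0.16 with array weights, 0.19 without the array of mouse 74 and -2.71 to 2.34 with 1 mouse left out. Trp53 in Sertoli cells (0.88) was -0.77 without the mice titled het and -0.54 to 1.70 with 1 mouse left out. Trp53 in germ cells (1.28) was -1.49 without the younger mice and -0.63 to 2.55 with 1 mouse left out. Trp73 between the control fractions (0.12) was -0.18 without the younger mice, -0.47 with array weights, -0.43 without the array of mouse 74 and -0.18 to 0.63 with 1 mouse left out. The median of endothelial markers in Sertoli cells (0.25) was -0.0074 to 0.57 with 1 mouse left out, that of Sertoli cell markers (0.17) was -0.068 without the mice titled het, that of integrins in germ cells (0.38) was -0.0079 within slide 3, and that of multiciliation regulators by the interaction term (0.35) was -0.064 within slide 1. Signal over background limits what could be measured, since 66.0% of probes were well above background on the knockout Sertoli and 65.8% on the control Sertoli arrays, against 77.3% and 75.6% on the germ arrays.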
